A study of Arabidopsis thaliana with 8 samples.

How the data were processed

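Total RNA from roots of 8 plant samples was labelled with biotin by the one-cycle protocol and hybridised to Affymetrix Arabidopsis expression arrays, per the labels' protocols. The 8 arrays fall into 4 groups of 2 biological replicates each, set by genotype (WT or fit) and iron supply. Each sample's group and replicate number came from its title.

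The deposited values are signal intensity per probe set. Per the submitters' processing notes they were made with RMA, which corrects background, normalises arrays by quantiles and summarises the probes of a set by median polish. The version of RMA and whether all 8 arrays were normalised together are not given in the sources used here. The deposited intensity values were on the linear scale, between 7.13 and 21060, with array medians between 111.9 and 117.8. Since a log2 scale had been assumed before the data were examined, log2 was taken of the deposited intensity values, and every test ran on those log2 values. RMA compresses differences between dim probe sets, so fold changes from a dim baseline are understated. Detection calls were not analysed here. The 25th percentile of the mean log2 signal was 4.96, and signal was not told apart from background here. For arrays, precision is limited by their number, 2 per group.

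The table held 22810 probe sets. The 64 control probe sets were left out of the tests, which ran on the other 22746. Genes were named through the platform table and the RefSeq gene table of the TAIR10.1 assembly, used for names only. Of the probe sets tested, 13513 named 1 gene (13356 distinct genes), 503 named several and were given no name, and 8730 were unnamed here. The RefSeq gene table gave no locus for 77 of the 13513. Unnamed probe sets are reported by their identifier; those in the text were chosen after their values were seen, by the size of their change. Where the RefSeq symbol was only a locus number, a common name in brackets comes from the gene lists fixed beforehand. No coordinates are given because the sources used here name no genome build for the array.

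Group means were fitted to all 8 arrays in 1 linear model per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with 4 residual and 3.82 prior degrees of freedom. The 5 comparisons were the iron response in WT, the iron response in fit, fit against WT under iron sufficiency, fit against WT under iron deficiency, and the difference of the iron responses (fit minus WT). p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05 with no fold limit. Errors of log2 fold changes are the standard errors of this fit (SE), and the errors of group means are SDs of 2 arrays.

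Before the data were examined, 18 gene lists with 224 members were fixed. They covered iron uptake and coumarin secretion, iron deficiency regulators, iron translocation, iron storage, transport of other metals, copper economy, the methionine cycle, phenylpropanoid synthesis, iron-sulfur and haem enzymes, phosphate starvation, sulfur starvation, jasmonate, root hairs, endodermis, stele, meristem, shoot photosynthesis and reference genes. A member was measured if its locus was named by a 1-gene probe set, taking the brightest. Only 31 members were measured, 181 had no probe set naming them alone, and 12 were left out because the RefSeq gene table gives their locus another name. The 4 lists with at least 3 measured members were tested with limma's camera (preset inter-gene correlation of 0.01, 2-sided, adjusted over the 4 lists within each comparison), and again with an estimated correlation and with fry. The other 14 lists were not tested, which departs from the plan, and their measured members are given as values. Member counts are also given adjusted over the list alone.

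Genes were named in the text by a rule fixed beforehand. It takes, per comparison, the 10 highest and 10 lowest called log2 fold changes among probe sets naming 1 gene whose groups do not overlap, with no such condition for the difference of responses. It adds up to 4 called members per list and, always, FIT, IRT1, FRO2, BHLH38, BHLH39, BHLH100, BHLH101 and FER1 where measured. Of the latter, only BHLH101 was named by a probe set, so the mutated gene FIT was not checked in these arrays. Overlaps of calls were tested with Fisher's exact test, 2-sided. For the pair of comparisons that share the WT iron-deficient arrays, 100 sets of arrays with no effect were simulated with the fitted spread, and for this pair and for the overlap of the WT and fit responses 100 more each, with errors of equal replicate numbers correlated between groups as measured.

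The fits were tested on simulated data: normal values around each probe set's mean over all arrays with the fitted spread, 5 simulations, 200 of 22746 probe sets changed. For the iron response in WT, 29.1% of changes of 1 on the log2 scale were recovered, 97.2% of changes of 2 and 100% of changes of 4, and 6.38% of calls were false. For the difference of the iron responses, the shares were 4.53%, 76.2% and 99.7%, with 6.03% of calls false. In 50 simulations over the 22746 probe sets, camera called the 9 regulators each time they were shifted by 1, and 2.67% of unshifted lists. All these simulated errors were independent between probe sets and between arrays. The rates therefore may not hold for the measured arrays, whose replicate deviations correlated between groups at up to r = 0.659.

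The alternatives planned before the data were examined were a second quantile normalisation, median centring, leaving out probe sets under the 40th percentile of mean signal, testing only probe sets naming 1 gene, a trended and robust variance, array weights, a replicate block, a fold limit of 1 on the log2 scale, only the 4 arrays compared, and leaving out each array in turn. For lists, they were an estimated correlation, fry and the mean over all probe sets of a gene. Chosen after seeing the data were a fit without the replicate 2 arrays of both iron-deficient groups, a fit with the ratio of 3' to 5' signal of the control transcripts as a covariate, and tests of 21 gene families.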

Results

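Gene expression in roots of Arabidopsis thaliana was measured in WT plants and in fit plants, which are mutated in FIT, the basic helix-loop-helix transcription factor known to drive iron uptake in the root epidermis. The plants spent 14 days on Gamborg medium and then 3 days with sufficient iron (50 µM iron as Fe(III)-EDTA) or without added iron and with 300 µM ferrozine, a chelator that binds ferrous iron. Each of the 4 groups held 2 arrays, and the labels call the replicates biological. Values are log2 signal intensities after RMA, on 22746 probe sets. The median log2 signal of the arrays lay between 6.81 and 6.88. No probe set named FIT, IRT1, FRO2, BHLH38, BHLH39, BHLH100 or FER1 on its own, so the mutation could not be checked from the signal of its gene.

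The arrays of replicate 2 of both iron-deficient groups differed from the other 6 in RNA quality measures. The control transcripts for actin, GAPDH and ubiquitin, which are probed at both ends, had a mean 3' to 5' signal ratio of 3.08 on the WT iron-deficient replicate 2 array and of 5.22 on the fit iron-deficient replicate 2 array, against 1.07 to 1.53 on the others. Their scores on the first principal component, which held 43.6% of the variance, were 31.5 and 68.8, against -24.5 to -9.08 on the others. Arrays of 1 group correlated with Pearson's r across probe sets between 0.963 for fit under iron deficiency and 0.991 for fit under iron sufficiency. These values do not set the groups apart. The fit iron-deficient replicate 1 array correlated more closely with every array of the other groups (0.974 to 0.986) than with its own replicate. The highest r, 0.994, was between WT iron-sufficient replicate 1 and fit iron-sufficient replicate 2. Probe sets are not independent replicates.

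**Figure D1:**
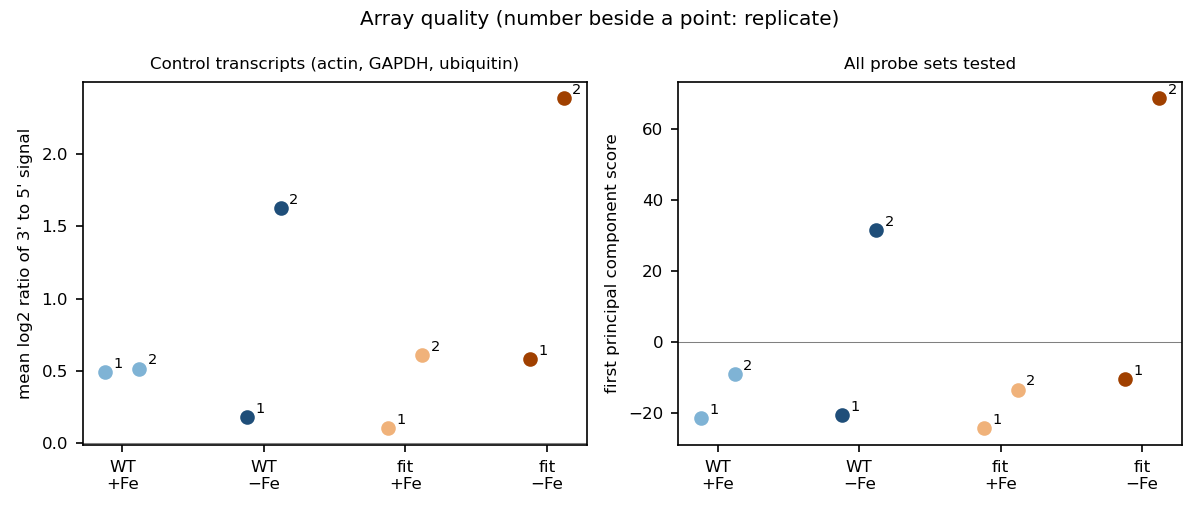
Array quality in the 4 groups. The left panel gives the mean log2 ratio of 3' to 5' signal over the control transcripts of actin, GAPDH and ubiquitin, the right panel the score on the first principal component of the probe sets tested, each point 1 array with its replicate number beside it. The replicate 2 arrays of both iron-deficient groups lie above the other 6, with log2 ratios of 1.62 in WT and 2.38 in fit against at most 0.61 elsewhere.

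The first comparison asked how WT roots respond to iron deficiency. Genes of coumarin synthesis and release, which mobilises iron outside the root, were higher in iron-deficient WT roots. AT3G12900 (S8H), the scopoletin hydroxylase that makes fraxetin, was 33.4-fold higher (log2 5.06, SE 0.44, limma adjusted p = 0.00314), with a mean log2 signal of 10.95 ± 0.34 against 5.89 ± 0.50 (SD, n = 2 each). BGLU42, a beta-glucosidase, was 6.36-fold higher, and AT3G13610 (F6'H1), the feruloyl-CoA hydroxylase at the start of coumarin synthesis, was 4.01-fold higher. Regulators of the iron deficiency response were higher too: AT1G47400 (IMA1), an IRON MAN peptide, by 30.3-fold and BHLH101, a transcription factor of subgroup Ib, by 17.1-fold. The vacuolar metal transporter AT3G58060 (MTP8) was 18.9-fold higher.

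Of the 4 measured members of the iron uptake and coumarin list, 3 were called higher in WT over all probe sets and 4 when adjusted over the list alone, the fourth being COSY, the coumarin synthase, at a log2 fold change of 0.72 (SE 0.21). The list was higher than the other probe sets (camera adjusted p = 9.09e-13; adjusted p = 0.00365 with an estimated correlation). This list was drawn up from general knowledge that includes earlier work on fit, which may include these samples, so it is not independent evidence of its direction. Of the 9 measured iron deficiency regulators, 5 were called higher and 7 when adjusted over the list alone (camera adjusted p = 2.49e-16; adjusted p = 0.00365 with an estimated correlation). Beside IMA1 and BHLH101 these included AT1G74770 (BTSL1) at 2.68 (SE 0.28), AT1G18910 (BTSL2) at 1.71 (SE 0.17), both hemerythrin-domain ubiquitin ligases, and PYE, a basic helix-loop-helix repressor, at 1.39 (SE 0.17). ILR3 and bHLH115, transcription factors of another subgroup, had 0.53 (SE 0.19) and 0.64 (SE 0.22) and passed over the list alone, while bHLH34 had -0.12 (SE 0.21) and bHLH104 0.25 (SE 0.19) and did not.

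Outside the lists, the named genes with the highest changes in WT were AT3G61930 at a log2 fold change of 5.82 (SE 0.20), the cytochrome P450 gene CYP71B5 at 4.70 (SE 0.17), FOLB1, a dihydroneopterin aldolase of folate synthesis, at 4.04 (SE 0.23), AT4G19370 at 3.87 (SE 0.45), AT1G73120 at 3.78 (SE 0.20) and AT3G07720 at 3.69 (SE 0.27). The unnamed probe set 253502_at, singled out after its values were seen, had the highest change of any probe set, 6.30 (SE 0.18), from a mean log2 signal of 4.13 to 10.43. Lower in iron-deficient WT roots were AT1G52820, by 35.7-fold (log2 -5.16, SE 0.47), AT3G49960, a class III peroxidase, at -2.35 (SE 0.34), AT2G36885 at -1.97 (SE 0.21), AT1G68650 at -1.73 (SE 0.17) and AT1G80320 at -1.57 (SE 0.22). So were petA, for cytochrome f in the plastid genome, at -1.56 (SE 0.19) and SAPX, for stromal ascorbate peroxidase, at -1.27 (SE 0.18). The 3 measured shoot photosynthesis markers were lower as a list (camera adjusted p = 0.0166), a call lost with an estimated correlation (adjusted p = 0.0979). None was called over all probe sets, and RCA, at -0.63 (SE 0.17), passed over the list alone. The iron-sulfur and haem list (SIR, SDH2-1 and ISU1) was not called (camera adjusted p = 0.161), with SIR, a sulfite reductase, passing over the list alone at -1.04 (SE 0.28).

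In all, 98 of 22746 probe sets were called in WT, 81 higher and 17 lower, of which 46 named 1 gene. The control ratio of 3.08 on WT iron-deficient replicate 2 stood against 1.41 and 1.43 on the WT iron-sufficient arrays. Calls made on 2 arrays per group need replicates that agree, so signs kept without 1 array say little here. The count was 33 and 41 without WT iron-deficient replicate 1 or 2, 32 and 26 without WT iron-sufficient replicate 1 or 2, 56 without either fit iron-sufficient array, which only the shared spread ties to this comparison, and 382 with the 3' to 5' ratio as a covariate. In each of the fits without 1 of these arrays all 98 kept their sign and 10 to 18 of the 21 named calls stayed, with S8H between 4.71 and 5.42 and BHLH101 between 3.82 and 4.37 over all alternatives.

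The second comparison asked which part of the response remains in fit. Regulators were higher in iron-deficient fit roots, while the coumarin genes had no called change. AT1G47400 (IMA1) was 17.7-fold higher (log2 4.14, SE 0.33, adjusted p = 0.00609), BHLH101 was 5.32-fold higher (2.41, SE 0.22, adjusted p = 0.00901), and PYE was 2.62-fold higher (1.39, SE 0.17, adjusted p = 0.0268). The largest change of a named gene was AT3G02480, at 22.3-fold (4.48, SE 0.24), followed by IMA1 and then AT5G09570, a small mitochondrial cysteine-rich protein, at 15.5-fold (3.95, SE 0.28). NDB4, an alternative NAD(P)H dehydrogenase of mitochondria, was 7.57-fold higher (2.92, SE 0.30).

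Of the 9 regulators, 3 were called higher in fit and 4 when adjusted over the list alone (camera adjusted p = 7.15e-06; adjusted p = 0.0448 with an estimated correlation). Of the 4 uptake and coumarin genes, 0 were called by limma, and over the list alone each had an adjusted p of 0.549 or more (camera adjusted p = 0.602), with S8H at 0.38 (SE 0.44), BGLU42 at 0.08 (SE 0.23), F6'H1 at -0.21 (SE 0.23) and COSY at -0.30 (SE 0.21). MTP8 had 0.01 (SE 0.22). The iron-sulfur and haem list was lower (camera adjusted p = 0.0290), with SIR at -0.70, SDH2-1 at -0.54 and ISU1 at -0.17, a call lost with an estimated correlation (adjusted p = 0.223). The shoot photosynthesis list was lower at a camera adjusted p of 0.0499, also lost with an estimated correlation (adjusted p = 0.223), with RCA at -0.67, LHCB4.1 at -0.45 and PORB at 0.01.

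Other named genes higher in iron-deficient fit roots were AT2G41730 at 3.67 (SE 0.43), AT5G25840 at 3.18 (SE 0.23), AT1G10875 at 3.00 (SE 0.30), AT1G73120 at 2.88 (SE 0.20), AT1G12030 at 2.65 (SE 0.26) and AT5G01670 at 2.64 (SE 0.25). The named genes called lower were AT3G49960 at -2.87 (SE 0.34), AT1G68650 at -2.09 (SE 0.17), AT2G36885 at -1.99 (SE 0.21), AT5G40510 at -1.79 (SE 0.24), AT4G25790 at -1.68 (SE 0.22), AT1G24575 at -1.65 (SE 0.19), SAPX at -1.51 (SE 0.18) and AT5G04970 at -1.45 (SE 0.20). The root hair expansins EXPA7 and EXPA18 had -1.28 (SE 0.33) and -1.23 (SE 0.31) in fit and were not called over all probe sets (limma adjusted p = 0.321 and 0.313).

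In fit, 46 probe sets were called, 30 higher and 16 lower, 24 of them naming 1 gene. The control ratio was 5.22 on fit iron-deficient replicate 2 against 1.07 and 1.53 on the fit iron-sufficient arrays. With a replicate block 145 were called, 55 higher and 90 lower, so the majority direction depended on the model. As in WT, signs kept without 1 array say little for calls that need replicates to agree. Without either fit iron-sufficient array 1 probe set was called, without either WT iron-sufficient array 28, with only the 4 arrays of fit 6, and with the 3' to 5' ratio as a covariate 147, of which 70 were higher and 77 lower. All 46 kept their sign in the fits without 1 array, where 1 to 17 of the 20 named calls stayed, and over all alternatives IMA1 lay between 3.66 and 4.55, BHLH101 between 2.26 and 2.56 and AT3G02480 between 4.18 and 4.78.

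The responses of WT and fit share no arrays and were set side by side. Among probe sets called higher, 17 were called in both genotypes, against 0.107 by chance (Fisher's exact test, p = 4.55e-35). They included IMA1, BHLH101, PYE, AT1G73120, AT3G02480, AT5G05250 and AT5G02580. Among those called lower, 5 were called in both, against 0.012 by chance (Fisher's exact test, p = 5.3e-13), and 4 of them were AT3G49960, AT2G36885, AT1G68650 and SAPX. Both responses use the shared spread, and replicates of equal number deviated alike (r = 0.659 between the iron-deficient groups). Simulated arrays with no effect and errors correlated between groups as measured shared 0.03 on average as higher and 0.02 as lower, and at most 1 each in 100 simulations. Those errors were drawn independently between probe sets, which Fisher's exact test assumes too. Neither therefore covers changes common to many probe sets of an array. Of the 81 probe sets called higher in WT, 61 had a positive change in fit, with a median log2 fold change of 2.12 in WT and 0.31 in fit. The 17 called lower in WT were all negative in fit, with medians of -1.86 and -1.36. Of the 30 called higher in fit, 28 were positive in WT, with medians of 2.34 in fit and 1.55 in WT. The 16 called lower in fit were all negative in WT, with medians of -2.01 and -0.63. Probe sets picked by calls in 1 genotype tend to change less in the other, so these medians do not measure what fit loses. Without either fit iron-sufficient array no probe set was shared in either direction. Without WT iron-sufficient replicate 1 or 2, 8 and 7 were shared as higher and 0 as lower, and without WT iron-deficient replicate 1 or 2, 10 and 9 as higher and 2 and 1 as lower.

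**Figure D2:**
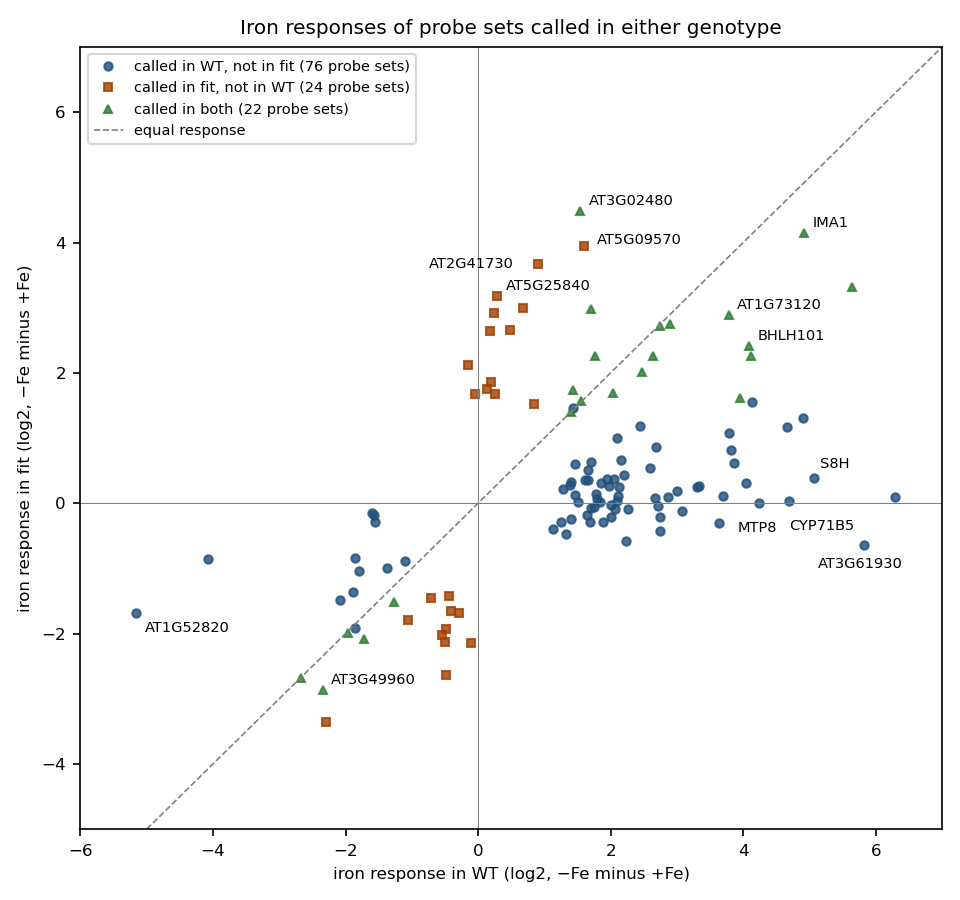
Iron responses of the 122 probe sets called in WT or fit. The x axis gives the log2 fold change of iron-deficient over iron-sufficient roots in WT, the y axis that in fit, each point 1 probe set, and the dashed line an equal response. IMA1, AT1G73120 and BHLH101 lie among the 22 called in both, S8H, MTP8, CYP71B5 and AT3G61930 at or below 0.38 on the fit axis.

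The third comparison asked how fit differs from WT when iron is sufficient. BHLH101 was 7.96-fold higher in fit (log2 2.99, SE 0.22, adjusted p = 0.0115), with a mean log2 signal of 9.14 ± 0.14 against 6.15 ± 0.09 (SD, n = 2 each). Over all alternatives the log2 fold change of BHLH101 lay between 2.89 and 3.09. The unnamed probe set 264751_at was 6.19-fold higher (2.63, SE 0.18). No probe set was called lower by limma. In either direction 418 of 22746 had an unadjusted p under 0.05, less than the share of 0.05 that no effect would give. The number was 1275 with array weights and 1119 with the 3' to 5' ratio as a covariate. The shared spread includes the iron-deficient arrays. Their replicates correlated at r = 0.977 in WT and 0.963 in fit, against 0.990 and 0.991 under iron sufficiency. The few calls therefore do not show that fit and WT were alike here. As a list, the 9 regulators were higher in fit (camera adjusted p = 6.92e-13; adjusted p = 0.00938 with an estimated correlation). Over the list alone, 3 passed: BHLH101, IMA1 at 2.08 (SE 0.33) and BTSL1 at 1.59 (SE 0.28). None of the 4 uptake and coumarin genes was called (camera adjusted p = 0.943), with log2 fold changes from -0.37 for BGLU42 to 0.10 for F6'H1. The shoot photosynthesis and iron-sulfur lists were not called (camera adjusted p = 0.943 for both).

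The 2 calls became 0 without any 1 of the 4 iron-sufficient arrays, 6 without either fit iron-deficient array, and 6 with only the 4 arrays compared. They became 4 with quantile normalisation, median centring, without dim probe sets or with a trended and robust variance, 18 with array weights, 20 with the covariate, 6 without the 2 arrays of high control ratio and 1 with only probe sets naming 1 gene.

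The fourth comparison asked how fit differs from WT under iron deficiency. The coumarin genes and MTP8 were lower in fit. S8H was 29.5-fold lower (log2 -4.88, SE 0.44, adjusted p = 0.00518), BGLU42 7.79-fold lower (-2.96, SE 0.23, adjusted p = 0.00242), F6'H1 4.30-fold lower (SE 0.23 on the log2 scale, adjusted p = 0.0135) and MTP8 18.9-fold lower (-4.24, SE 0.22, adjusted p = 0.000312). ZIP9, a metal transporter of the ZIP family, was 4.50-fold lower (-2.17, SE 0.26). AT3G02480 was 40.6-fold higher in fit (5.34, SE 0.24, adjusted p = 0.000123).

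Of the 4 uptake and coumarin genes, 3 were called lower in fit and 4 over the list alone (camera adjusted p = 7.07e-16; adjusted p = 0.00447 with an estimated correlation), COSY having -0.93 (SE 0.21); as above, this list is not independent evidence. Of the 9 regulators, BTSL2 was called lower at -1.55 (SE 0.17) and none was called higher. Over the list alone BHLH101, at 1.31 (SE 0.22, adjusted p = 0.0891 over all probe sets), and IMA1, 2.47-fold higher, passed, and the list as a whole was not called (camera adjusted p = 0.432). The iron-sulfur list and the shoot photosynthesis list were not called (camera adjusted p = 0.432 and 0.987).

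Further genes lower in fit under iron deficiency were AT3G61930 at -6.20 (SE 0.20), CYP71B5 at -4.63 (SE 0.17), FOLB1 at -3.62 (SE 0.23), ATPMEPCRB, a pectin methylesterase, at -3.43 (SE 0.22), AT4G09110 at -3.40 (SE 0.26), AT5G38820 at -3.12 (SE 0.23) and AT1G73120 at -2.46 (SE 0.20). The unnamed probe set 253502_at had -6.84 (SE 0.18). Higher in fit, beside AT3G02480, were AT5G25840 at 3.29 (SE 0.23), AT2G41730 at 3.15 (SE 0.43), AT5G01670 at 3.02 (SE 0.25), AT5G09570 at 2.54 (SE 0.28), PUB19, a U-box ubiquitin ligase, at 2.53 (SE 0.18), NDB4 at 2.50 (SE 0.30), AT1G12030 at 2.39 (SE 0.26), AT1G10875 at 2.32 (SE 0.30) and AT4G36700, 4.29-fold higher (SE 0.24 on the log2 scale). The root hair expansins EXPA7 and EXPA18 had -1.304 (SE 0.33) and -1.03 (SE 0.31) and were not called over all probe sets (limma adjusted p = 0.365 and 0.553).

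**Figure D3:**
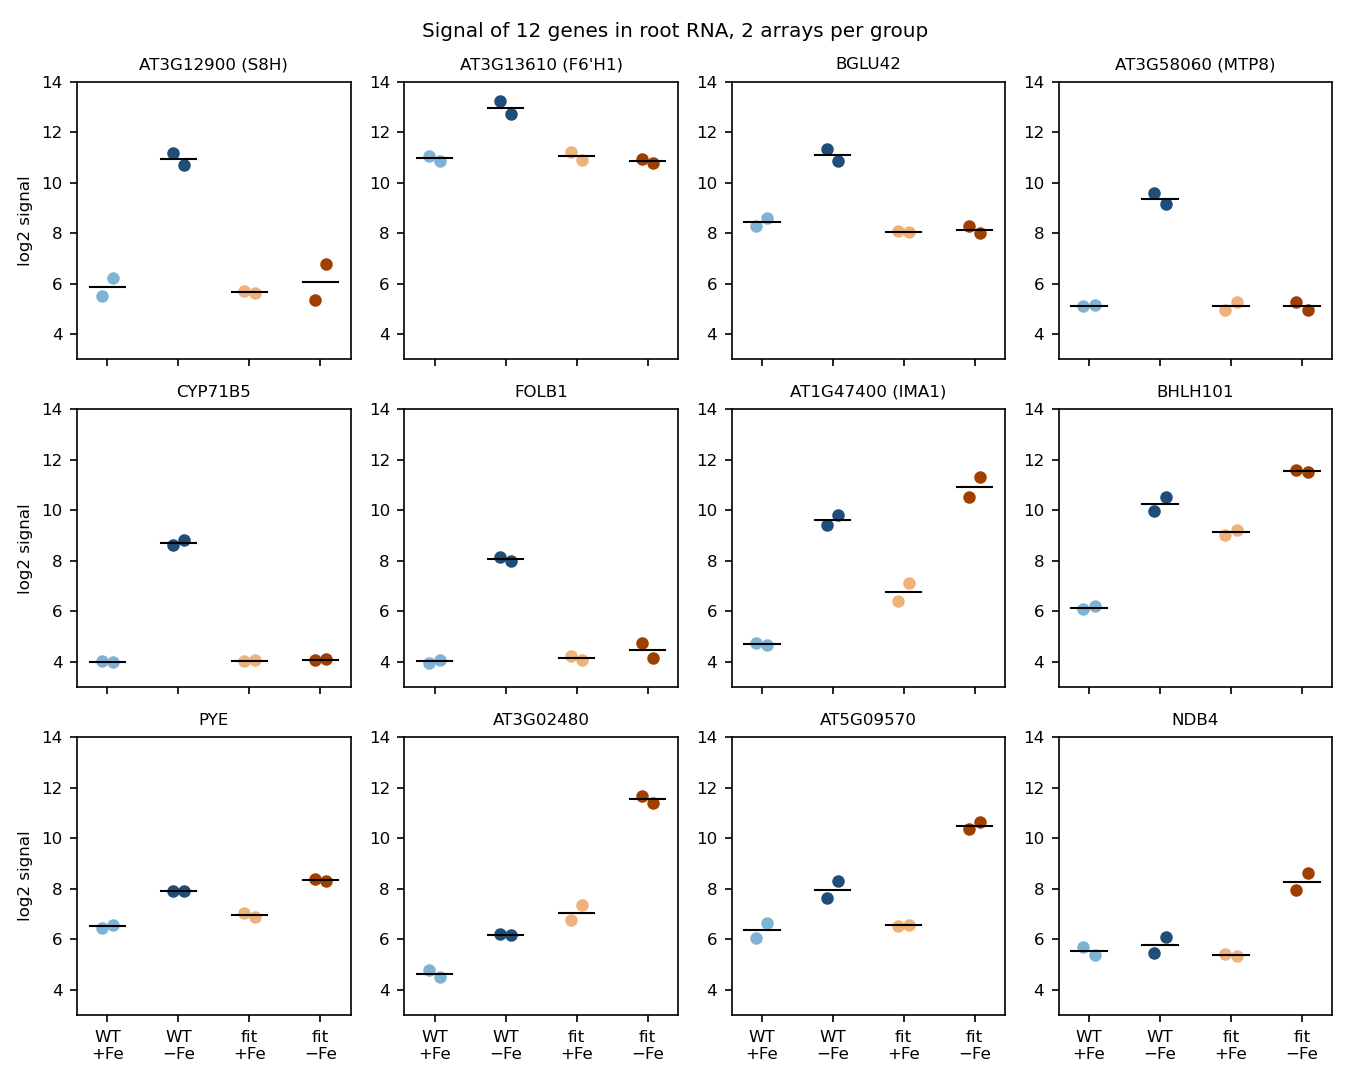
Log2 signal of 12 genes on each array in the 4 groups, points for the 2 arrays of a group and a line for their mean. S8H, F6'H1, BGLU42, MTP8, CYP71B5 and FOLB1 are higher in iron-deficient WT than in the other 3 groups, while IMA1, BHLH101 and PYE are higher under iron deficiency in both genotypes, and AT3G02480, AT5G09570 and NDB4 are highest in iron-deficient fit.

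Under iron deficiency, 62 probe sets were called between fit and WT, 17 higher and 45 lower in fit, 33 of them naming 1 gene, and both groups hold an array of high control ratio (5.22 in fit, 3.08 in WT). The count was 21 and 28 without WT iron-deficient replicate 1 or 2, 33 without either WT iron-sufficient array, 31 without either fit iron-sufficient array, 30 with array weights, 10 with only the 4 arrays compared and 188 with the covariate; 13 to 23 of the 23 named calls stayed when 1 array was left out. Of the 81 probe sets called higher in the iron response of WT, 36 were among the 45 lower in fit. These comparisons share the WT iron-deficient arrays, and independent lists of these sizes would share 0.16. Simulated arrays with no effect and independent errors shared 0.31 on average and at most 2 in 100 simulations. With errors of equal replicate numbers correlated between groups as measured they shared 0 in each of 100. Both simulations drew errors independently between probe sets, so changes common to many probe sets of an array were not covered. The 2 shared arrays were too few to split between the comparisons.

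The fifth comparison tested the difference of the iron responses, fit minus WT. The response was smaller in fit for AT3G61930 (difference -6.45 on the log2 scale, SE 0.29, adjusted p = 0.000241), CYP71B5 (-4.67, SE 0.24, adjusted p = 0.000471), MTP8 (-4.23, SE 0.32, adjusted p = 0.00536), FOLB1 (-3.74, SE 0.32, adjusted p = 0.0133) and AT3G07720 (-3.57, SE 0.38, adjusted p = 0.0358). AT3G07720 already had a mean log2 signal of 11.55 in iron-sufficient fit roots, against 9.65 in WT. The response was also smaller in fit for AT4G09110 at -3.19 (SE 0.37), AT5G38820 at -2.95 (SE 0.32) and ATPMEPCRB at -2.81 (SE 0.31). It was larger in fit for AT3G02480 at 2.93 (SE 0.34) and AT5G25840 at 2.89 (SE 0.32).

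The 4 uptake and coumarin genes passed only over the list alone, with S8H at -4.68 (SE 0.62), BGLU42 at -2.59 (SE 0.32), F6'H1 at -2.21 (SE 0.33) and COSY at -1.03 (SE 0.30), and the list was lower (camera adjusted p = 1.82e-14; adjusted p = 0.00540 with an estimated correlation). Of the 9 regulators, 0 were called over all probe sets by limma and 3 over the list alone, BTSL1 at -1.82 (SE 0.40), BTSL2 at -1.79 (SE 0.25) and BHLH101 at -1.68 (SE 0.31, adjusted p = 0.243 over all probe sets). As a list their difference was negative (camera adjusted p = 5.56e-07, and adjusted p = 0.0174 with an estimated correlation), while IMA1 had -0.78 (SE 0.47) and PYE 0.00 (SE 0.24). The list mean in fit against WT was 0.90 under iron sufficiency and 0.15 under iron deficiency. The negative difference of the list mean therefore reflects a higher iron-sufficient level in fit, not a lower iron-deficient one. BTSL2 alone was called lower in fit under iron deficiency, at -1.55 (SE 0.17). EXPA7 and EXPA18 had -1.72 (SE 0.47) and -1.37 (SE 0.44) and were not called over all probe sets. The iron-sulfur and shoot photosynthesis lists were not called (camera adjusted p = 0.5003 and 0.8455).

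The difference was called for 17 probe sets, 15 of them with a smaller value in fit. The control ratios of 3.08 and 5.22 enter both responses. Signs kept without 1 array say little here too, because such calls need replicates that agree. The count was 5 and 6 without WT iron-deficient replicate 1 or 2, 11 and 26 without fit iron-deficient replicate 1 or 2, 3 without any 1 of the 4 iron-sufficient arrays and 93 with the covariate, with all 17 keeping their sign. The calls of AT3G02480 and AT5G25840 ended with array weights, without the 2 arrays of high control ratio and in 7 of the 8 fits without 1 array, while their values stayed between 2.64 and 3.23 and between 2.69 and 3.10.

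Lists with under 3 measured members gave values only. In WT and in fit, the iron responses were -0.10 and -0.11 for VTL3 and -0.21 and -0.38 for VTL4 (iron storage), 0.26 and -0.08 for CCS (copper economy), 0.30 and -0.05 for HCT (phenylpropanoids), -0.05 and 0.21 for BGLU28 (sulfur starvation), and -0.62 and -0.52 for MCM7 (meristem). The reference genes UBC21 and TIP41 had 0.17 and 0.04 in WT and -0.07 and -0.14 in fit, and the root hair genes EXPA7 and EXPA18 had 0.45 and 0.14 in WT. ZIP9 had 1.54 (SE 0.26) in WT, with an adjusted p of 0.0795 over all probe sets, and -0.07 (SE 0.26) in fit. No member of the lists for iron translocation, the methionine cycle, phosphate starvation, jasmonate, endodermis or stele was measured.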

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

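Chosen only after the result was seen were the 2 tests on the arrays that stand apart, the counts of calls kept without arrays, the fit without the 2 arrays and the covariate. The tests of median ratios and of the mitochondrial list were written down before they were run. The mitochondrial list itself was written after the genes that prompted it were seen.

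The iron response differed between fit and WT, by a test of the difference itself, for AT3G61930 (-6.45 on the log2 scale, fit minus WT), CYP71B5 (-4.67), AT3G58060 (MTP8, -4.23), FOLB1 (-3.74), AT3G07720 (-3.57), AT4G09110 (-3.19), AT5G38820 (-2.95), ATPMEPCRB (-2.81), AT5G25840 (2.89) and AT3G02480 (2.93). Among unnamed probe sets it differed for 253502_at (-6.20) and 262412_at (-3.94). As lists, the iron uptake and coumarin genes differed by a mean of -2.63 and the iron deficiency regulators by -0.75. For the regulators, the list mean in fit against WT was 0.90 under iron sufficiency and 0.15 under iron deficiency, so a higher iron-sufficient level in fit gives that value.

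The probe sets with a smaller iron response in fit had a median difference of -3.57 over 15 probe sets. RNA quality of the arrays that stand apart is argued against for 13 of the 15, which are called in a fit that holds neither of the 2 arrays; the calls of the unnamed 253658_at and 264751_at ended there, with fewer arrays to estimate the spread from, at -2.59 (SE 0.35) against -2.75 (SE 0.32) and -2.16 (SE 0.27) against -2.32 (SE 0.25). That 1 array decides the difference is argued against for 3, AT3G61930, CYP71B5 and 253502_at, called in all 8 fits without 1 array; where calls of the other 12 ended, their values were 0.895 to 1.10 times as large, with a median SE of 0.383 against 0.319. The kept sizes had medians 1.01 times as large without both arrays and at least 0.95 times without 1. These sizes neither point to the 2 explanations nor decide against them, although 0.75 had been set as the bound beforehand. The reason is that calls made on 2 arrays per group need replicates that agree. With the 3' to 5' ratio as a covariate all 15 stayed called, with a median 0.958 times as large. That fit does not decide either, since replicates that agree at unlike ratios leave the covariate little to change. The uptake list was fixed before these data were examined, but with knowledge of earlier fit work that may include these samples. It is therefore not independent evidence of its direction. Its mean difference was -2.63 with all arrays. It was -2.84 without the 2 and -2.48 to -2.77 without 1.

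The probe sets higher in fit than in WT under iron deficiency had a median of 2.39 over 17 probe sets. Without the 2 arrays that stand apart, all 17 were still higher in fit, from 1.41 to 5.45, with a median 1.04 times as large. For the reasons given above, neither these sizes nor the calls in that fit decide on RNA quality of the arrays that stand apart. With the 3' to 5' ratio as a covariate all 17 stayed called, with a median 0.954 times as large, which does not decide either. A mitochondrial stress response in fit may be a candidate explanation. A list of 15 such genes, written before its test and without the genes that prompted it, had 9 measured members. Their median was 0.398 (camera p = 2.41e-06, and p = 0.0160 with an estimated correlation). By limma 0 of the 9 were called and 3 had an unadjusted p under 0.05, against 62 and 1168 of all 22746; without the 2 arrays 1 was called, 6 instead of 8 were positive, and the median was 0.388. The 17 were picked for their calls in this comparison and the 9 were not, so the 2 medians cannot be set against each other. How much of the change of the 17 the hypothesis could account for stays open.

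Signal in the control transcripts, which no comparison uses, set 2 arrays apart. The mean log2 ratio of 3' to 5' signal was 1.62 on WT iron-deficient replicate 2 and 2.38 on fit iron-deficient replicate 2, against at most 0.612 on the iron-sufficient arrays. Degraded or truncated RNA stays open: the lower of the 2 lay 1.01 above the highest of the other 6, but this is the measure that set the arrays apart and does not test it. Less labelled root cRNA on the array stays open too, since the mean log2 signal of the hybridisation spike-ins was at least 0.39 above that of the other 6. Iron deficiency alone is not enough, because replicate 1 of both iron-deficient groups had 0.18 and 0.584; no biological explanation was tested.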

How the results depend on the processing

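Chosen after seeing the data were the fit without the 2 arrays of low 5' signal and the 3'/5' covariate. With that covariate, and with a replicate block, all 75 named calls stayed called. The 75 named calls kept their direction under every alternative that tested them; 74 stayed called with quantile normalisation, 75 with median centring, 73 with a trended and robust variance, 61 with array weights, 65 without the 2 arrays, and 29 of 65 with only the 4 arrays compared. Leaving out 1 array in turn left 37 to 66. A left-out array leaves its group with 1 array, assumed to vary like the others. Kept directions say little about robustness, because calls made on 2 arrays per group need replicates that agree. In comparisons of 2 groups, the groups of each named call did not overlap. Neither leaving out 1 array nor using only the 4 arrays compared could therefore reverse a named sign there. The cause of a changed count was not tested unless fewer probe sets or arrays give it.

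Probe sets called in the order WT response (98), fit response (46), fit against WT under sufficiency (2) and under deficiency (62), and difference of responses (17) became 44, 24, 1, 32 and 10 with only probe sets naming 1 gene, which has fewer probe sets, and 382, 147, 20, 188 and 93 with the covariate. Leaving out 1 array gave 26 to 140, 1 to 69, 0 to 6, 21 to 75 and 3 to 26. With only the 4 arrays compared, the fit response had 6, sufficiency 6 and deficiency 10. With array weights, sufficiency had 18 and deficiency 30. Sufficiency also had 4 with quantile normalisation, 4 with median centring, 4 without dim probe sets, 4 with a trended and robust variance, and 6 without the 2 arrays. The fold limit changed no count.

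The overlap of calls higher in both responses (17) was 40 with the covariate and 0 to 14 with 1 array left out; that of calls lower in both (5) was 21, and 9 without the 2 arrays, and 0 to 6. The 3 lists called in the fit response were 1 with an estimated correlation, quantile normalisation, without dim probe sets, with the mean over probe sets or with fry, and 1 to 3 with 1 array left out.

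The arrays share only replicate numbers, 2 per group, and no common batch is named. A replicate block gave 201, 145, 4, 134 and 40 calls (in the fit response 55 higher and 90 lower, and 70 and 77 with the covariate, against 30 and 16) and overlaps of 26 and 15; deviations of the replicates correlated between groups with r from 0.131 to 0.659. What signal over background limits was not analysed here.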

Other observations

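The 21 gene families tested here were chosen after seeing the data: genes that share the letters of their symbol, with at least 10 members, and genes of the plastid genome.

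Signal of genes encoded in the plastid genome was lower in iron-deficient WT roots. Of 69 genes, 57 had a negative log2 fold change, with a median of -0.677. The family was called by camera (adjusted p = 4.05e-15), a call lost with an estimated correlation (adjusted p = 0.860). How well the one-cycle labelling captures plastid transcripts was not examined here. Of the family, petA was called. In fit the median was 0.0203 with all arrays (camera adjusted p = 0.963), but without the 2 arrays of high control ratio it was -0.233 and the family was called lower there too (camera adjusted p = 0.00171). The difference of the responses had a median of 0.666 (camera adjusted p = 2.97e-11; adjusted p = 0.785 with an estimated correlation) and 0.508 without the 2 arrays. Under iron deficiency the family was higher in fit than in WT, with a median of 0.328 (camera adjusted p = 0.000343; adjusted p = 0.931 with an estimated correlation), a call also lost without the 2 arrays (median 0.241, camera adjusted p = 0.0918). Under iron sufficiency it was lower in fit, with 53 of 69 negative and a median of -0.368 (camera adjusted p = 1.03e-08; adjusted p = 0.758 with an estimated correlation). The medians kept their sign with quantile normalisation and with median centring, at -0.632 and -0.642 in WT.

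In the iron response of fit, 2 small families were lower. The 10 expansin genes of the EXPA family, which loosen cell walls, had a median of -0.496 (camera adjusted p = 0.0292), with only 6 negative. The 11 PRA genes had a median of -0.32 (camera adjusted p = 0.0232), with 9 negative. Both calls were lost with an estimated correlation (adjusted p = 0.372). Under iron sufficiency the 11 glutathione transferase genes of the GSTU family were higher in fit than in WT as a set, with a median of 0.313 and 4 negative. This call (camera adjusted p = 0.00793) was also lost with an estimated correlation (adjusted p = 0.758). The signs of these medians held with quantile normalisation and with median centring. By limma 0 members were called in these comparisons, which says little where 46 and 2 of 22746 probe sets were called, and 5 EXPA, 2 PRA and 2 GSTU genes had an unadjusted p under 0.05.

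Of the mitochondrial stress genes measured, AT2G21640 (UPOX) had the largest difference between fit and WT under iron deficiency, 3.66 (SE 0.60, adjusted p = 0.0864), then AT2G32020 at 1.72 (SE 0.29) and AT2G04050 at 1.35 (SE 0.25), while AT5G64400 had -0.06 (SE 0.18).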
